A study of Mus musculus with 12 samples.

How the data were processed

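ATAC-seq was performed by the authors on livers of 19 to 20 week old male wild-type C57BL/6N mice that received vehicle (distilled water), 10 mg/kg atorvastatin or 100 mg/kg PCN by gavage on 4 days and were fasted for 12 h. Per the labels, groups held 9 to 10 mice, 100 to 160 mg of liver and 100000 nuclei were used, and tagmentation ran for 45 min at 37 °C. The labels do not state whether each library came from a single mouse. Of these groups, control, atorvastatin and PCN have 4 libraries each. A pravastatin group at 10 mg/kg is not analysed here. The labels name Trimmomatic, STAR 2.7.9a, bedtools 2.30.0, HOMER 4.10 and the build mm10, without their roles. They do not state the rule for an enhancer or a promoter, the counting tool, or any filter.

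The deposited tables hold expected counts, unnormalised and in steps of 0.5, for 406518 enhancer regions and 43511 promoters named by RefSeq transcript. The unit was read from the values. The counts were rounded to whole numbers before fitting. Of the 406518 enhancer regions, 406433 fall into 12 width classes, each with its highest relative count in a different library. Since 64% of regions overlap another, regions are not independent. Of 43511 promoters, 42203 were matched to the reference annotation. The annotation gives no strand, so an enhancer without a named gene was assigned to the protein-coding gene body nearest to it, and counted in a list only within 50 kb, instead of by the nearest transcription start. Total counts per library are in the results, and p values measure the spread between these libraries only.

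Both were fitted separately in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood test), all 12 libraries in a single fit with group as the only factor. Benjamini-Hochberg adjustment covered all regions tested per comparison, separately for enhancers and promoters, with a threshold of 0.05. This left 41908 promoters of 24603 symbols and 182115 enhancers. Errors (SE) of edgeR's log2 fold changes are the absolute log2 fold change over the square root of the quasi-likelihood F, with normal 95% intervals. They are therefore approximate. Log2 CPM used a prior count of 2. The 3 comparisons were PCN with control, atorvastatin with control, and PCN with atorvastatin. The tests, the lists, the rule for named genes and the first set of alternatives were chosen before the data were examined.

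The 23 fixed lists comprise 13 pathway, 3 hepatocyte and 7 other cell type lists. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, which does not compare a list with other genes. The lowest adjusted p by fry for promoters was 0.37, 0.91 and 0.78 in the 3 comparisons. For promoters, each gene was represented by the promoter of highest mean CPM. For enhancers, all tested regions assigned to a gene were used. Genes were named by this rule: up to 10 regions per direction with the largest change among those past the threshold with no overlap between groups. Where fewer than 5 passed, the 3 regions of smallest p per direction were named as not past it. All 25 core genes by their most open promoter, and up to 4 called members per list, were named too. Treatment effects were compared by correlation of log2 fold changes across regions, against 50 simulated data sets and with the 4 controls split into separate pairs.

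Alternatives were DESeq2 size factors, library totals, loess offsets, no filter, minimum counts of 30, a threshold of 0.1, DESeq2 1.42.0, limma-voom, fits of 2 groups, the replicate number as a block, a surrogate variable as covariate (sva 3.50.0), a distance of 20 kb and leaving out each library. Chosen after seeing the data were leaving out control 3 and atorvastatin 3 (median enhancer correlation under 0.5), and combinations of that with other settings, a single region per overlapping locus, the share of counts in the most open promoters as a covariate, voom sample weights, unrounded counts and a single promoter per gene. The files were read with the R packages GenomicRanges 1.54.1 and data.table, version 1.17.8. The fit was tested on simulated data with 200 regions changed 1.5-, 2- or 4-fold. Motif tests and GC correction were left out, since no genome sequence was used here.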

Results

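Open chromatin was profiled by ATAC-seq, an assay in which a transposase cuts accessible DNA, in livers of male wild-type C57BL/6N mice aged 19 to 20 weeks. The mice received by gavage, on 4 days, distilled water as vehicle, 10 mg/kg atorvastatin or 100 mg/kg pregnenolone 16α-carbonitrile (PCN). Atorvastatin is a statin, a cholesterol-lowering drug, and PCN is an agonist of the mouse pregnane X receptor (PXR), a nuclear receptor that controls drug metabolism. Each of the 3 groups held 4 libraries, for 12 libraries in all. Counts were deposited for 406518 enhancer regions and 43511 promoters.

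In the enhancer table the control libraries 1 to 4 held total counts of 5517722, 3918854.5, 1530063.5 and 1256648.5. The atorvastatin libraries held 2671493.5, 13078975.5, 8081817 and 8891817 counts, and the PCN libraries 5942707, 4252321, 6698425 and 3499412. In the promoter table the totals were 10493197, 6263142.5, 2368263 and 1679054 for control, 4218336.5, 15336000.5, 7831940 and 13226739 for atorvastatin, and 8265553, 4872850.5, 10021771.5 and 5240354.5 for PCN. Control 3 and atorvastatin 3 stood apart from the other 10 libraries. Their median correlations with the others across enhancer regions were 0.369 and 0.0476. The medians of the other 10 libraries were 0.708 to 0.847, and these correlated with each other at 0.653 to 0.93. Across promoters, the medians of control 3 and atorvastatin 3 were 0.766 and 0.79. Those of the other 10 were 0.92 to 0.969, with correlations among these 10 of 0.895 to 0.981. By width, 24.8% of enhancer regions are of the class of atorvastatin 3. There it held a mean of 5.04 CPM, against a median of 0.834 in the other libraries. The enhancer correlation of atorvastatin 3 was not taken without these regions. Regions are not independent replicates, so these correlations carry no p. In control 3, 68.6% of enhancer regions held 0 counts, and in atorvastatin 3 27.4% did. Control 4, which was kept, lay between them at 37.99%, so this share did not set atorvastatin 3 apart. Because of the low correlations, every count of regions was also taken without control 3 and atorvastatin 3. This alternative was chosen after the data were seen.

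**Figure D1:**
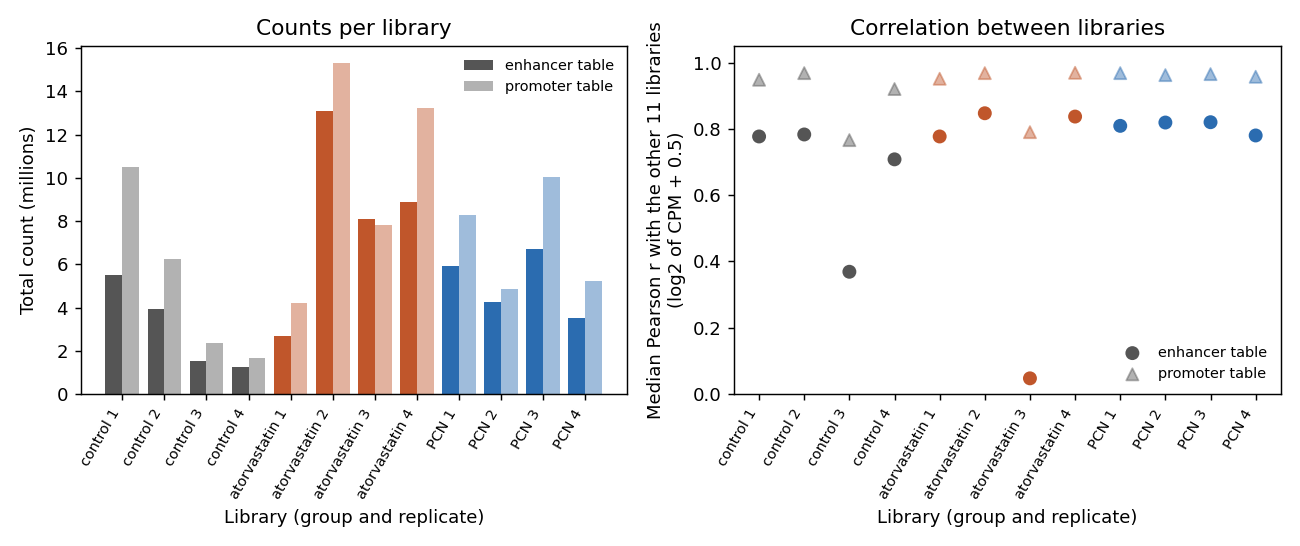
Total counts per library (left, bars from 0, axis scaled as labelled) and the median Pearson correlation of each library with the other 11 (right) in the enhancer and promoter tables, by library and group. Control 3 and atorvastatin 3 lie lowest in both tables, at 0.369 and 0.0476 for enhancers.

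The comparison of PCN with vehicle asked which hepatic regions opened or closed under a PXR agonist. Promoters of hepatocyte and metabolic genes lay higher with PCN as groups, and those of stellate cell and fibroblast markers lay lower. The hepatocyte core list, genes of plasma proteins and other main products of hepatocytes, had a median log2 fold change of 0.41, and of 0.25 without the 2 low-correlation libraries, with 18 of 20 promoters above 0 (camera adjusted p = 1.1e-05). Near 41 genes of PXR- and CAR-associated drug metabolism, 611 of 778 enhancer regions lay above 0. Their median log2 fold change was 0.39 (camera adjusted p = 0.00069), and 0.20 without the 2 low-correlation libraries. These list calls were lost with an estimated correlation within lists (adjusted p = 0.47 for each promoter list and 1 for the enhancer list). No single promoter or enhancer passed the test.

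Among promoters, 15 of the 23 fixed lists passed the camera test with the preset correlation, 14 higher and 1 lower. Cholesterol synthesis and uptake genes, the targets of SREBP2, lay above 0 for 28 of 33 promoters, with a median log2 fold change of 0.23 (adjusted p = 3.7e-05). Gluconeogenesis and fasting genes did so for 22 of 22, with a median of 0.26 (adjusted p = 5.3e-05). Fatty acid oxidation and ketogenesis genes (26 of 35, median 0.29, adjusted p = 0.00023) and genes of bile acid and sterol disposal (25 of 32, median 0.23, and 0.10 without the 2 low-correlation libraries, adjusted p = 0.00023) followed. PXR/CAR-associated drug metabolism genes lay above 0 for 36 of 55 promoters, with a median of 0.19 (adjusted p = 0.0037). The remaining lists on the higher side were nuclear receptors and hepatic transcription factors (29 of 33, adjusted p = 0.00051), periportal hepatocyte (19 of 26, 0.00079), stress and immediate-early genes (27 of 30, 0.0017), fatty acid and triglyceride synthesis (23 of 30, 0.01), sex-biased liver genes (21 of 31, 0.01) and NRF2 targets (21 of 27, 0.039). The circadian clock (18 of 22, 0.00044) and cell cycle (21 of 30, 0.04) lists were also higher, but with loess offsets, a scaling that depends on abundance, their medians changed sign to -0.03 and -0.01. Stellate cell and fibroblast markers lay below 0 for 20 of 24 promoters, with a median of -0.32 (adjusted p = 0.0024). Each of these 15 calls was lost with an estimated correlation (adjusted p = 0.47 for each). Without the 2 low-correlation libraries, many medians lay inside the central range of random lists matched on CPM. Examples are gluconeogenesis (0.19 against 0.12 to 0.29) and bile acid disposal (0.10 against 0.02 to 0.18). Cholesterol, fatty acid oxidation, circadian, NRF2, stress, cell cycle and nuclear receptor lists lay inside too. Drug metabolism, sex-biased, fatty acid synthesis, periportal and hepatocyte core lists lay at or above its upper end. Pericentral hepatocyte (adjusted p = 0.082), acute phase (0.094), liver endothelial (0.075), lymphocyte (0.075), neutrophil (0.28), Kupffer cell (0.41), cholangiocyte (0.43) and erythroid (0.69) lists did not pass.

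At single promoters with all 12 libraries, adjusted over the list alone, 1 gene passed in the cholesterol list and 0 in the other 22 lists. That gene was Ebp, a sterol isomerase of cholesterol synthesis, at a log2 fold change of 1.03 ± 0.28 (SE, n = 4 libraries per group, higher in 4 of 4), with an adjusted p of 0.92 over all promoters by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without the 2 low-correlation libraries, 2 promoters passed over the list alone in each of the fatty acid oxidation, gluconeogenesis and sex-biased lists. In each of the cholesterol, periportal and hepatocyte core lists 1 did. List members named next were chosen after their values were seen. Among drug metabolism genes, the carboxylesterase gene Ces2c was at 0.73 ± 0.30 and Abcc2, a canalicular export pump, at 0.65 ± 0.27. In fatty acid oxidation, the acyl-CoA thioesterase genes Acot3 and Acot4 were at 1.09 ± 0.38 and 1.14 ± 0.45. In sterol disposal, Abcg5 and Abcg8, which together export sterols into bile, were at 0.61 ± 0.27 and 0.64 ± 0.27. The stellate marker Des, which encodes desmin, was at -1.10 ± 0.48. Of the 25 core genes fixed before the data were examined, 19 lay above 0 with PCN. The largest was G6pc, the glucose-6-phosphatase of glucose release, at 1.03 ± 0.34 (edgeR adjusted p = 0.92, higher in 4 of 4 libraries), and Fgf21, a fasting hormone, lay lowest at -0.43 ± 0.20 (edgeR adjusted p = 0.92, lower in 4 of 4). Cyp3a11, the classical PXR target, was at 0.64 ± 0.33 with a 95% interval of 0 to 1.28 (edgeR adjusted p = 0.92, above the control mean in 3 of 4 libraries). Cyp2b10, the classical CAR target, was at -0.38 ± 0.41. The gene of PXR itself, Nr1i2, was at -0.30 ± 0.29 and at 0.17 ± 0.19 without the 2 low-correlation libraries.

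By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 41908 promoters and 0 of 182115 enhancer regions passed for PCN against control, with 1572 promoters and 3511 enhancers at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0 in both tables. The promoters with the smallest p values were Mir6978, a microRNA gene on chromosome 17 inside the complement gene C3 (1.06 ± 0.25), Ebp and Ankrd40 (0.77 ± 0.22) on the higher side, each higher in 4 of 4 libraries. On the lower side they were Gm10007 (-1.42 ± 0.40), Garnl3 (-2.52 ± 0.71) and Clip4 (-2.34 ± 0.68), each lower in 4 of 4, the last 2 falling to -1.33 and -1.17 without control 3. All had an adjusted p of 0.92 by edgeR. The corresponding enhancers, all at an adjusted p of 1 by edgeR, lay in Trip10 (1.14 ± 0.30, chromosome 17, 57233219 to 57233401), 790 bp from Vegfa, which encodes an endothelial growth factor (1.58 ± 0.42), and near Hnrnpll (1.10 ± 0.30). Those lower with PCN lay 570 bp from the proteasome gene Psma3 (-2.10 ± 0.50), near Coq2 (-3.14 ± 0.80) and in Pheta1 (-2.40 ± 0.64), the last 2 falling to -1.79 and -1.42 without control 3. By width, the Psma3 region is of the class of control 4, and the Coq2 and Pheta1 regions of that of control 3. Both libraries are in the group where these regions lay higher, and an effect of this on the values was not tested. The Trip10, Vegfa and Hnrnpll regions are of the class of atorvastatin 3, outside this comparison. In tests on simulated data with the same spread, 10 of 67 promoters changed 2-fold and 46 of 66 changed 4-fold were found, and 0 of 67 and 1 of 66 enhancers, so single enhancers that changed up to 4-fold were rarely detectable with all 12 libraries. Without the 2 low-correlation libraries 30 of 66 enhancers changed 4-fold and 28 of 67 promoters changed 2-fold were found. Without the 2 low-correlation libraries, 6 promoters of 5 genes passed by edgeR with only the groups in the design, all higher with PCN, and 0 enhancers. In the same 10 libraries a replicate block gave 124 promoters, 110 higher and 14 lower, and 20 enhancers, 16 of them lower. Voom with sample weights in all 12 libraries called 268 promoters, 220 higher and 48 lower.

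Of the enhancer lists, 6 passed for PCN: drug metabolism and cholesterol synthesis (349 of 441 regions above 0, median 0.34, and 0.14 without the 2 low-correlation libraries, adjusted p = 0.0028) on the higher side, and 4 marker lists of other cell types on the lower side. Neutrophil (60 of 89 below 0, median -0.24, adjusted p = 2.1e-08), erythroid (25 of 26, -0.45, 0.00014) and stellate cell (30 of 46, -0.26, 0.00067) regions lay below 0, but without the 2 libraries the erythroid list did not pass (median -0.37, adjusted p = 0.069). The lymphocyte list was lower relative to other regions (adjusted p = 0.029, mean -0.01) though its median was 0.08. The neutrophil regions lay near 7 genes, the erythroid near 4, the stellate near 8 and the lymphocyte near 8. Those of drug metabolism lay near 41 genes and those of cholesterol synthesis near 22. Regions of the same gene were entered separately, so these counts and camera p values overstate the number of independent observations. Each of the 6 calls was lost with an estimated correlation (adjusted p = 0.89 for neutrophil and 1 for the others). With all 12 libraries, 0 regions passed when adjusted over the list alone. Without the 2 libraries, 10 regions did in the lymphocyte list and 1 in the drug metabolism list. The median log2 fold change of all enhancers was 0.172 with TMM scaling and -0.111 with loess offsets, and that of all promoters 0.01 with TMM and -0.104 with library totals only, so list changes are relative to these medians, and camera tests them so. The remaining 17 enhancer lists did not pass, with liver endothelial (adjusted p = 0.24) the only one of these whose mean (0.03) and test differed in sign.

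The promoter lists depended on the scaling and on the control libraries: 5 passed with loess offsets (hepatocyte core, drug metabolism, bile acid disposal, periportal and sex-biased, all higher), 0 with loess offsets and without the 2 low-correlation libraries, 14 without those libraries alone, and 5 without control 1. Of the 14, 11 were among the first 15. Lost were drug metabolism (adjusted p = 0.1, median 0.11), sex-biased genes (0.21, median 0.06), NRF2 targets (0.1) and cell cycle (0.15), and gained were pericentral, endothelial and lymphocyte lists. Enhancers of drug metabolism genes kept the higher side and passed with loess offsets (adjusted p = 0.0016), without the 2 libraries (0.00037) and with both changes (0.00072), each by camera with the preset correlation, but not with an estimated correlation (adjusted p = 1 with all 12 libraries and 0.56 without the 2). Without control 4 the number of enhancer lists was 12.

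**Figure D2:**
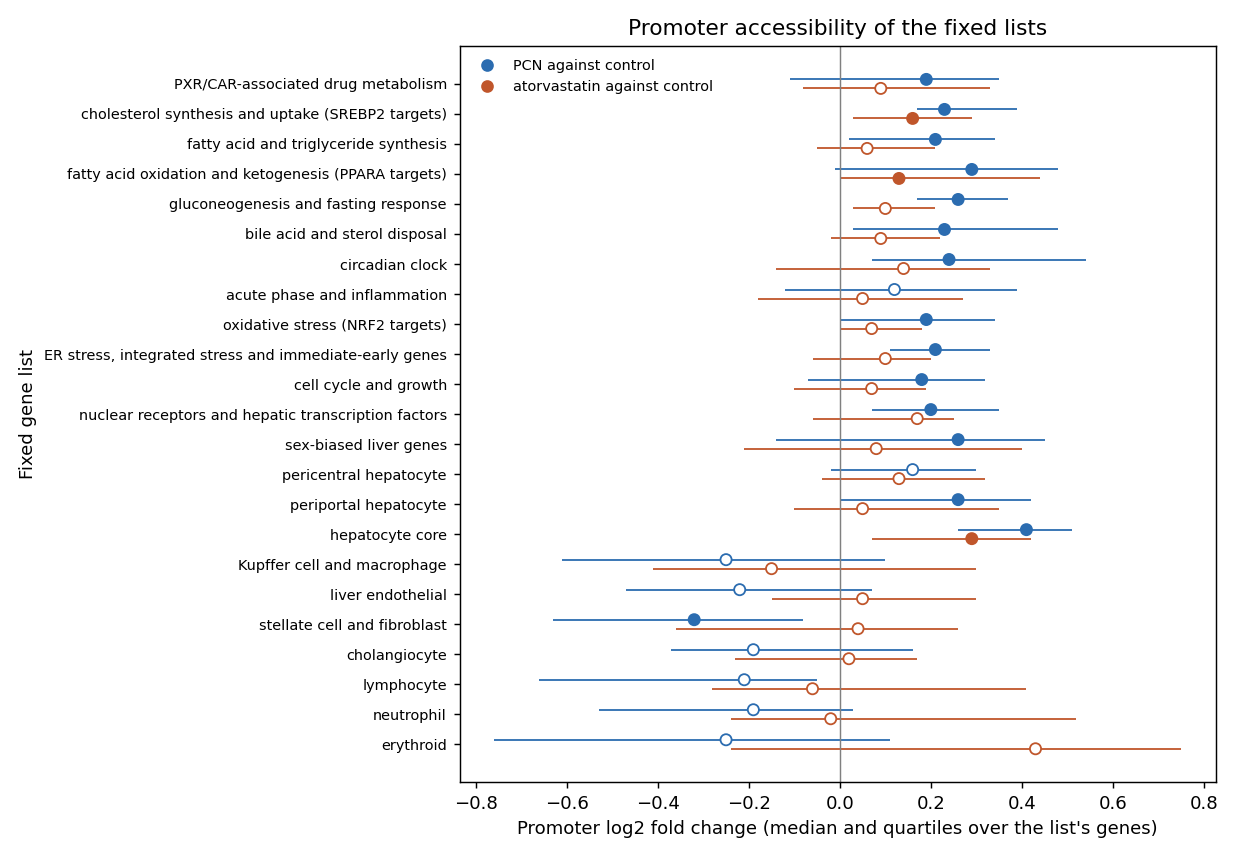
Median log2 fold change of promoters (points) with the quartiles over the genes (lines) for the 23 fixed lists, for PCN and atorvastatin against control, with filled points for lists past the camera threshold with the preset correlation. For PCN, the hepatocyte core list lies highest at 0.41 and stellate cell and fibroblast lowest at -0.32, and with loess offsets the PCN medians of the circadian and cell cycle lists change sign.

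The comparison of atorvastatin with vehicle asked which hepatic regions a statin opened or closed. Promoters of hepatocyte products, of cholesterol synthesis and of fatty acid oxidation lay higher with atorvastatin as groups. The hepatocyte core list had a median log2 fold change of 0.29 with 17 of 20 promoters above 0 (camera adjusted p = 0.02). Cholesterol synthesis and uptake genes, targets of the factor that statins activate, had a median of 0.16 with 25 of 33 above 0 (adjusted p = 0.033), and fatty acid oxidation and ketogenesis genes 0.13 with 26 of 35 above 0 (adjusted p = 0.033). Each of these 3 calls was lost with an estimated correlation (adjusted p = 0.94 for each). Without the low-correlation libraries, the cholesterol median of 0.14 lay inside the central range of random lists matched on CPM (0.09 to 0.23). The fatty acid oxidation median of 0.25 lay above its range (0.07 to 0.21), and the hepatocyte core median of 0.25 at the upper end (0.07 to 0.25). No single promoter or enhancer passed the test.

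In the cholesterol list, Ebp was at 0.82 ± 0.28 and Aacs, an acetoacetyl-CoA synthetase, at 0.56 ± 0.26. In the fatty acid oxidation list, Acot3 and Acot4 were both at 1.02, with SE 0.38 and 0.44, and the ketone body enzyme gene Bdh1 was at 0.67 ± 0.22. These members were chosen after their values were seen. Adjusted over the list alone, 0 promoters passed in any of the 23 lists with all 12 libraries. Without the 2 low-correlation libraries, 3 passed in the fatty acid oxidation list, 2 in the sex-biased list and 1 in the endothelial list. Drug metabolism genes did not pass as a list (36 of 55 above 0, median 0.09, adjusted p = 0.5). Of the 25 core genes, 18 lay above 0, with G6pc highest at 0.80 ± 0.34, and at 0.49 ± 0.21 without the 2 low-correlation libraries (edgeR adjusted p = 1, above the control mean in 3 of 4 libraries). Cyp3a11 was at 0.63 ± 0.32, at 0.23 without atorvastatin 3, at 0.46 without control 3 and at 0.06 ± 0.22 without both. The fatty acid transporter gene Cd36 lay lowest at -0.56 ± 0.53. The other lists had adjusted p values of 0.5 for gluconeogenesis, bile acid disposal, NRF2 targets, nuclear receptors, pericentral, periportal and erythroid. They were 0.58 for circadian clock, sex-biased and endothelial genes, 0.59 for lymphocyte, 0.6 for fatty acid synthesis, 0.65 for acute phase, cell cycle and cholangiocyte, 0.7 for stellate, 0.71 for stress genes and Kupffer cells and 0.94 for neutrophil. In 4 of these lists median, mean and test differed in sign: stellate (median 0.04, test lower), cholangiocyte (0.02, lower), lymphocyte (mean 0.02, lower) and neutrophil (mean 0.07, lower).

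By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 promoters and 0 enhancers passed for atorvastatin against control, with 807 and 4361 at an unadjusted p under 0.05. DESeq2 called 1 promoter, Mir6978, and 0 enhancers, and limma-voom 0 in both. Mir6978 lay highest by rank of p, at 1.48 ± 0.25 (edgeR adjusted p = 0.22, higher in 4 of 4 libraries than every control). Next came Hamp, the gene of the iron-regulating hormone hepcidin, at 1.17 ± 0.31, and the microRNA gene Mir126b at 0.81 ± 0.21. On the lower side were Mir6965 (-1.40 ± 0.32), 4933431G14Rik (-1.27 ± 0.32) and Elmo2 (-1.08 ± 0.33), each with an edgeR adjusted p of 1 and lower in 4 of 4 libraries. Among enhancers, a region 1949 bp from Hamp was at 3.69 ± 0.78 (chromosome 7, 30940236 to 30940418, higher in 4 of 4 libraries, edgeR adjusted p = 1), and at 2.67 ± 0.55 without the 2 low-correlation libraries. It held 0.665 ± 0.806 CPM in controls, 11.2 ± 9.61 with atorvastatin and 5.13 ± 1.37 with PCN (SD, n = 4 each). Atorvastatin 3 was its highest library, at 24.7 CPM, and by width the region is of that library's class. The other enhancers of smallest p were in Trip10 (1.20 ± 0.30) and near Hsf2bp (2.18 ± 0.57), and, lower, in Grap (-3.97 ± 1.07, and -2.69 without the 2 libraries), in Klf3 (-2.83 ± 0.78, and -1.94) and near Coq2 (-2.82 ± 0.78, and -1.49 without control 3). By width, Trip10 is of the class of atorvastatin 3, and Grap, Klf3 and Coq2 of those of control 2, control 4 and control 3. All these are libraries of the group where the region lay higher. Hsf2bp is of the class of PCN 2.

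Enhancer regions near cholesterol synthesis genes lay higher with atorvastatin (328 of 441 above 0, median 0.33, and 0.15 without the 2 libraries, camera adjusted p = 0.0065). Regions near neutrophil (63 of 89 below 0, median -0.41, 0.00049), erythroid (21 of 26, -0.47, 0.0012) and lymphocyte markers (56 of 109, -0.02, 0.026) lay lower, but without the 2 libraries the erythroid list did not pass (median -0.19, adjusted p = 0.38). Each of these 4 calls was lost with an estimated correlation (adjusted p = 0.96 for each). With all 12 libraries, 0 regions passed when adjusted over the list alone. Without the 2 libraries, 2 regions passed in the drug metabolism list and 2 in the sex-biased list. The regions of the 4 called lists lay near 22 cholesterol, 7 neutrophil, 4 erythroid and 8 lymphocyte genes, and were entered separately. The median of all enhancers was 0.125 with TMM scaling and -0.013 with loess offsets. Of the other 19 enhancer lists none passed, and in 6 of them median or mean and test differed in sign. The number of promoter lists past the threshold was 0 without control 1, without control 3, without atorvastatin 2, without atorvastatin 4 or with loess offsets, 6 without atorvastatin 1, 10 without control 4, 13 without atorvastatin 3 and 11 without both low-correlation libraries. Without those 2 libraries, 4 promoters passed by edgeR with only the groups in the design, all higher with atorvastatin, and 0 enhancers. In the same 10 libraries limma-voom called 16 promoters, 2 higher and 14 lower, and 141 enhancers, 135 of them lower. Voom with sample weights in all 12 libraries called 171 promoters, 15 higher and 156 lower.

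The comparison of PCN with atorvastatin asked where the 2 treatments differed, in doses of 100 and 10 mg/kg. Promoters of liver pathways lay higher with PCN and those of endothelial and stellate markers lay lower, as groups. Gluconeogenesis and fasting genes had a median log2 fold change of 0.19 with 20 of 22 above 0 (camera adjusted p = 7.7e-05), but 0.05 with 15 of 22 and no call without the 2 low-correlation libraries (adjusted p = 0.13). Drug metabolism genes had a median of 0.10 with 39 of 55 above 0 (adjusted p = 0.01). Stellate cell and fibroblast markers lay below 0 for 23 of 24 promoters (median -0.38, adjusted p = 0.00046) and liver endothelial markers for 22 of 24 (-0.29, 0.00058), with medians of -0.14 and -0.16 without the 2 libraries. Each call was lost with an estimated correlation (adjusted p = 0.58 for each).

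In all, 15 promoter lists passed, 12 higher and 3 lower with PCN. Bile acid disposal (26 of 32 above 0, adjusted p = 0.00024), periportal hepatocyte (21 of 26, 0.0027), cholesterol synthesis (24 of 33, 0.007), hepatocyte core (18 of 20, 0.0078), fatty acid synthesis (22 of 30, 0.01), sex-biased genes (21 of 31, 0.013) and cell cycle (20 of 30, 0.035) were on the higher side. The circadian clock (21 of 22, 0.00024), stress genes (26 of 30, 0.00024) and nuclear receptors (25 of 33, 0.0027) were too, but with loess offsets each of their medians was -0.02. Erythroid markers were lower (14 of 16 below 0, median -0.31, adjusted p = 0.043). Without the 2 low-correlation libraries this was gone (8 of 16 above 0, median -0.01, camera adjusted p = 0.98). The other lists had adjusted p values of 0.067 (fatty acid oxidation), 0.12 (acute phase and NRF2 targets), 0.13 (lymphocyte), 0.14 (neutrophil), 0.42 (pericentral), 0.48 (Kupffer cell) and 0.7 (cholangiocyte). Adjusted over the list alone, 0 promoters passed in any list. Of the 25 core genes, 18 lay above 0 with PCN, but 11 without the 2 low-correlation libraries. Cyp3a11 was at 0.01 ± 0.31, with a 95% interval of -0.60 to 0.62, and at 0.41 ± 0.19 without the 2 low-correlation libraries (edgeR adjusted p = 1). G6pc was at 0.23 ± 0.33 with an interval of -0.42 to 0.87, and Hmgcs1, a cholesterol synthesis enzyme gene, at 0.30 ± 0.29.

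By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 promoters and 0 enhancers passed for PCN against atorvastatin, with 306 and 847 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 in both tables. The promoters of smallest p were the lens gene Lenep (0.77 ± 0.29), the noncoding RNA gene AU019990 (0.74 ± 0.28) and the adiponectin gene Adipoq (0.74 ± 0.30) on the higher side, and Dbndd2 (-1.01 ± 0.32, and -0.50 without atorvastatin 3), Gm5622 (-2 ± 0.67) and H2-M10.6 (-0.54 ± 0.53 without the 2 low-correlation libraries) on the lower. All had an edgeR adjusted p of 1 and lay on 1 side of the atorvastatin mean in 4 of 4 libraries. The enhancers of smallest p, on the same terms, lay near Olfr541 (1.11 ± 0.42) and Krt18 (1.00 ± 0.38) and 74778 bp from Bod1, the nearest gene though beyond the 50 kb used for lists (2.92 ± 1.12), and, lower, near Car12 (-2.75 ± 0.76), Lef1 (-3.19 ± 0.93, and -1.84 without atorvastatin 3) and Mycn (-2.18 ± 0.65). By width, Olfr541 and Bod1 are of the classes of PCN 1 and PCN 4, and Car12 of that of atorvastatin 1. Lef1 and Mycn are of the class of atorvastatin 3, and Krt18 of that of control 2. Of the enhancer lists, Kupffer cell and macrophage regions passed on the higher side (69 of 89, near 8 genes, median 0.37, camera adjusted p = 0.00099). This call was lost with an estimated correlation (adjusted p = 0.97). Without the 2 libraries the median of this list was 0.19 (adjusted p = 0.022). Promoters of the same list lay the other way with all 12 libraries (6 of 24 above 0, median -0.24). Drug metabolism regions (504 of 778 above 0, median 0.13) had an adjusted p of 0.31, and of 0.019 without the 2 low-correlation libraries, which was lost with an estimated correlation (0.8). The median of all enhancers was 0.062 with TMM scaling and -0.074 with loess offsets. In 7 of the other enhancer lists median or mean and test differed in sign. The number of promoter lists fell to 5 without atorvastatin 3, 6 without atorvastatin 1, 5 without both low-correlation libraries, 5 with loess offsets and 3 with both of these changes. Left without the 2 libraries were drug metabolism, sex-biased and periportal genes on the higher side and endothelial and stellate markers on the lower, and the hepatocyte core median went from 0.11 to -0.01. For enhancers it was 0 without atorvastatin 1, 4 without atorvastatin 3 or PCN 3, 3 without control 2, 3 or 4, and 2 without atorvastatin 4, PCN 1 or PCN 2.

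Whether the 2 treatments moved the same regions was examined across all regions and at single promoters. Hamp, Mir6978, Tnfsf14, which encodes a TNF-family cytokine, and the noncoding RNA gene Gm29684 were higher than control under both treatments once the 2 low-correlation libraries were left out. These 4 promoters, with AU019990 for PCN alone, were the only ones called in these comparisons by edgeR with TMM scaling and only the groups in the design, and all but Mir6978 and, for atorvastatin, Hamp were named after their values were seen. Hamp (chromosome 7, 30942368 to 30944029) rose by 1.37 ± 0.24 with PCN and 1.64 ± 0.26 with atorvastatin, with adjusted p values of 0.0018 and 5.5e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It stood at 22.3 ± 2.98 CPM in 3 controls, 68.1 ± 29.6 in 3 atorvastatin and 57.2 ± 9.9 in 4 PCN libraries (SD), and every treated library lay above every control. Mir6978 (57217172 to 57217228 on chromosome 17) rose by 1.15 ± 0.22 and 1.41 ± 0.22 (adjusted p = 0.0047 and 6.1e-05 by edgeR), also in every treated library. Tnfsf14, 9.79 kb from C3, rose by 1.24 ± 0.22 and 1.20 ± 0.22 (adjusted p = 0.0017 and 0.0035 by edgeR), in 3 of 4 PCN and 2 of 3 atorvastatin libraries. Gm29684 rose by 1.07 ± 0.21 and 1.09 ± 0.22 (adjusted p = 0.01 and 0.014 by edgeR), in 4 of 4 and 2 of 3. AU019990 rose by 0.91 ± 0.19 with PCN (adjusted p = 0.029 by edgeR, 4 of 4). C3 itself was at 0.77 ± 0.25 and 0.71 ± 0.26 without passing (adjusted p = 0.79 and 0.91 by edgeR), and Hamp2, the hepcidin paralog, at -0.27 ± 0.39 and -0.40 ± 0.41.

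With all 12 libraries none of these passed by edgeR with only the groups in the design, while DESeq2 called Mir6978 for atorvastatin. By edgeR without control 3 alone or atorvastatin 3 alone 0 promoters passed too. Control 3 held 48.6 CPM at Hamp, 56.2 at Tnfsf14 and 43.1 at Gm29684, within the treated range, and 33.1 at AU019990, above every PCN library. With all 4 controls, 3 of 4 PCN libraries lay above every control at Hamp and 1 of 4 at Tnfsf14. At Gm29684 and AU019990 0 of 4 did, and at Mir6978 4 of 4. For atorvastatin it was 3 of 4 at Hamp, 1 of 4 at Tnfsf14 and Gm29684, and 4 of 4 at Mir6978. With loess offsets in the same 10 libraries Hamp passed under both treatments (1.18 ± 0.18 and 1.43 ± 0.18, adjusted p = 0.0058 and 0.00019 by edgeR) and Mir6978 under atorvastatin (adjusted p = 0.015 by edgeR). Also called there were Necab2 for PCN (0.81 ± 0.14, adjusted p = 0.036 by edgeR) and 4 promoters of Fbf1 for atorvastatin (0.97 ± 0.16, adjusted p = 0.011 by edgeR), while the calls of Tnfsf14 (adjusted p = 0.32 and 0.86 by edgeR), Gm29684 (0.6 and 0.86) and AU019990 (0.23) ended. Their log2 fold changes moved little, to 1.07 ± 0.25 and 1.00 ± 0.26, 1.03 ± 0.26 and 1.04 ± 0.27, and 0.87 ± 0.19. The call of Mir6978 for PCN also ended, at 0.98 ± 0.20 (adjusted p = 0.23 by edgeR). DESeq2 without the 2 libraries called Hamp and Necab2 for PCN and Hamp and Mir6978 for atorvastatin. With the share of counts in the most open promoters as a covariate in those 10 libraries, Mir6978 (1.28 ± 0.20, edgeR adjusted p = 0.02) and Necab2 passed for PCN, and Mir6978 (1.56 ± 0.21, 0.00097) and Hamp (1.41 ± 0.22, 0.0056) for atorvastatin, so the call of Hamp for PCN ended there (1.14 ± 0.21, edgeR adjusted p = 0.064, from 1.37 ± 0.24). With this covariate and all 12 libraries Mir6978 passed for atorvastatin (1.51 ± 0.21, edgeR adjusted p = 0.043). Leaving out 1 more library moved the number of promoters from 6 to between 3 (without control 1 or control 2) and 20 (without control 4) for PCN, and from 4 to between 2 (without atorvastatin 2) and 20 (without atorvastatin 1), with 17 without control 4, for atorvastatin. Across promoters, the log2 fold changes of the 2 treatments correlated at r = 0.764, against 0.545 in simulated unchanged groups that share the controls, and across enhancers at 0.711 against 0.561. With separate controls for each treatment, 2 libraries each, the mean r over 6 assignments was -0.1 for promoters (-0.219 to 0.011) and 0.002 for enhancers (-0.051 to 0.034). So no correlation across all regions was left once the controls were not shared, which argues against a response shared across regions. The 6 assignments reuse the same 4 controls, and promoters and regions are not independent replicates. At single promoters a shared response could not be told from differences among the controls by these values.

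**Figure D3:**
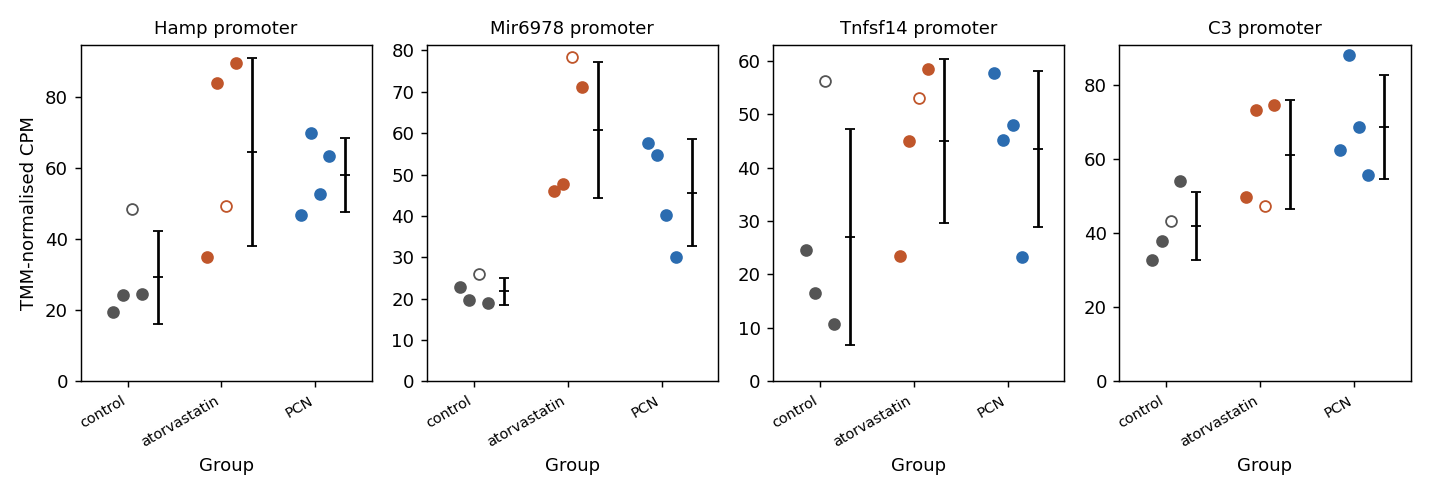
TMM-normalised CPM of the Hamp, Mir6978, Tnfsf14 and C3 promoters per library in the 3 groups, with mean and SD of 4 libraries as bars and control 3 and atorvastatin 3 as open points. Hamp stands at 48.6 CPM in control 3, within the range of the treated libraries.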

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

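The tests on the 2 low-correlation libraries, on Hamp and Mir6978 against single controls, on the share of hepatocyte nuclei, on the low-correlation libraries as a source of the list changes, and on the structure of the splits were chosen only after the result was seen.

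In 195 tests of a group of 4 libraries (21 on library measures and 174 on named regions), 12 values stood far from the other 3. Chance flags about 1 in 20 groups, or 9.75. Of the 12, 9 lie in control 3 or atorvastatin 3. Each is given with its gap to the nearest library as a share of the group's range. In atorvastatin 3, 27.4% of enhancer regions were at 0 counts (share 0.894), the median enhancer correlation was 0.0476 (0.912) and the median promoter correlation 0.79 (0.899). Its log2 CPM was lowest at the Klf3 enhancer (-1.07, share 0.89) and highest at the Cyp3a11 promoter (5.29, share 0.916). Control 3 was highest at the Coq2 enhancer (5.22, share 0.88) and lowest at the promoters of Cyp2c55 (0.552, share 0.837), Hmgcs1 (4.62, share 0.87) and G6pc (2.09, share 0.85). Further values were Cd36 in atorvastatin 4 (3.61, highest, share 0.854), G6pc in atorvastatin 1 (4.27, lowest, share 0.832) and Cpt1a in PCN 1 (5.82, lowest, share 0.916).

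Control 3 and atorvastatin 3 stood apart from the other 10 libraries. Depth alone is argued against, since after thinning to equal totals their highest median enhancer correlation was 0.33, where the others reached 0.559 to 0.684. A swap between groups is argued against, since neither correlated above 0.4 with any library across enhancers, or above 0.776 and 0.858 across promoters, where the others reached at least 0.653 and 0.895 with each other. Low signal over background may contribute in atorvastatin 3, where the share of counts in the 10% most open promoters was 22.9%, the lowest of 12, but not in control 3, at 28.8%. No biological explanation was tested.

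Without the 2 libraries, Hamp and promoters near C3 were higher under both treatments. A gain of the whole stretch within 500 kb is argued against, since the highest median log2 fold change of neighbouring genes was 0.03. A median over so many genes cannot exclude a gain of a shorter stretch. On one side of Hamp, Usf2 was at 0.55 with PCN and 0.59 with atorvastatin, and Lsr at 0.39 and 0.4. On the other side Hamp2 was at -0.27 and -0.4. Next to C3, Trip10 was at 0.21 and 0.16. A raised share of hepatocyte nuclei is argued against, since the hepatocyte core median reached only 0.25. A single control among the 3 kept (1, 2 and 4) is argued against for Hamp and Mir6978, whose smallest log2 fold change against any of these was 0.96. For the 4 promoters as a set it stays open, with 0.69 at Tnfsf14 and 0.5 at Gm29684, which lies on chromosome 10. Control 3 was not part of this test. It held 48.6 CPM at Hamp, 56.2 at Tnfsf14 and 43.1 at Gm29684, within the treated range, and 25.9 at Mir6978, below every treated library. With the share of counts in open promoters as a covariate, 2 promoters passed for each treatment, and Hamp no longer did for PCN (1.14 ± 0.21, edgeR adjusted p = 0.064). A response to both treatments and a difference among the 3 controls both stay open.

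Liver lists lay higher with PCN and, of the other cell type lists, stellate cell markers passed as lower, as did endothelial (adjusted p = 0.017) and lymphocyte markers (0.031) without the 2 libraries, though with loess offsets the circadian and cell cycle medians change sign. The 2 low-correlation libraries as the only source are argued against by an adjusted p of 0.001 (camera with the preset correlation, hepatocyte core, median 0.25) without them, but with an estimated correlation it was 0.6. Lower signal over background in the controls may be the source and cannot be told apart from a treatment effect: the hepatocyte core and stellate medians lay at percentiles 98.3 and 2.38 of random lists matched on CPM, at the edges of the central 95% (0.25 against 0.25 and -0.37 against -0.37), the share of counts in open promoters was 29.8 ± 3.34% in control and 32.7 ± 3.67% in PCN libraries (SD, n = 4 each), and leaving out 1 library gave 5 to 18 lists past the threshold and loess offsets without the 2 libraries 0. A larger share of hepatocyte nuclei stays open too. Without the 2 libraries 7 of 7 other cell type medians lay under 0 with PCN and 7 of 7 with atorvastatin. These signs cannot decide it, since random lists matched on CPM mostly lay under 0 too. With PCN their central 95% was -0.47 to -0.17 for lymphocyte, -0.44 to -0.12 for neutrophil and -0.4 to -0.11 for Kupffer cell lists. For cholangiocyte lists it was -0.24 to 0.05. The difference between hepatocyte and other markers had an exact two-sided permutation p of 0.257 for PCN with all 12 libraries and 0.543 without the 2. Induction by PCN stays open as untested.

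Chance was examined by splitting them in other ways. Among 35 splits of the promoters, 35 gave as many calls as the real 0 for PCN with control (highest other 0), 35 for atorvastatin with control (real 0, highest other 7670) and 35 for PCN with atorvastatin (real 0, highest other 0). For the lists, 8 splits gave as many as the real 15 (highest other 20), 25 as many as 3 (highest other 20) and 15 as many as 15 (highest other 21). Among enhancers, 35 of 35 splits gave as many calls as the real 0 in each comparison (highest others 0, 3 and 0), and 6, 7 and 27 splits gave as many lists as the real 6, 4 and 1 (highest others 11, 11 and 8). Without the 2 libraries, 4 of 35 splits gave as many promoters as the real 6 for PCN with control (highest other 1122) and 16 as many lists as 14 (highest other 20). For PCN with atorvastatin 35 gave as many promoters as 0 (highest other 55) and 29 as many lists as 5 (highest other 20). Where the real count is 0 every split gives as many, so those splits decide nothing. For the lists and the 6 promoters chance cannot be excluded. For atorvastatin with control, 10 splits are too few for a share under 0.05, with 4 splits as large as the real 4 promoters (highest other 9193) and 5 as large as the real 11 lists (highest other 21). Splits that call several times the real count point to a structure of the samples. In 3 of the 4 promoter series in which any split called promoters, the split with most calls parted the libraries without overlap by the share of counts in the most open promoters, such as 22.9 to 28.8% against 30.2 to 34% for the split with 7670 promoters.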

How the results depend on the processing

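With all 12 libraries, the count of changed regions was 0 in both tables and all 3 comparisons under every alternative chosen beforehand except DESeq2 for atorvastatin promoters (1). Under those alternatives there were 2428 log2 fold changes of 111 pairs of a named region and a comparison. Of these, 2399 differed from the main fit by less than the mean within-group SD of log2 CPM. Of the others, 28 moved further and 1 passed the threshold. No named region passed in the main fit, so a lost or reversed call could not occur, and direction was not checked. On simulated data 1 of 66 enhancers changed 4-fold was recovered, and 30 of 66 without the 2 low-correlation libraries. GC correction and motif alternatives were not run, for want of a genome.

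With an estimated correlation 0 lists passed in all 6 results, with or without the 2 low-correlation libraries. With loess offsets 5, 0 and 5 promoter lists passed (PCN, atorvastatin, PCN with atorvastatin) and 3 enhancer lists in the last, and with loess offsets and without the 2 libraries 0, 0 and 3 promoter and 4 enhancer lists. A distance of 20 kb gave 3 enhancer lists for PCN with atorvastatin. With the replicate number as a replicate block, 0 regions and 15, 3 and 15 promoter lists passed. Deviations of same-numbered libraries from their group means correlated over 0.1 in 7 of 12 pairs for enhancers (-0.015 to 0.15) and 6 of 12 for promoters (-0.42 to 0.5), and in 7 of 9 without the 2 libraries in both tables. Not every pair did, so the libraries were treated as ones that share only a number, though a batch by number stays open. As a hint from the data, 10 of 12 pairs correlated best with their own number for enhancers (9 of 9 without the 2 libraries) and 3 of 12 for promoters (3 of 9). Leaving out 1 library gave 5 to 18, 0 to 13 and 5 to 19 promoter lists, and 5 to 12, 3 to 6 and 0 to 4 enhancer lists.

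The following were chosen after seeing the data. Without the 2 libraries, 6 promoters passed for PCN and 4 for atorvastatin, with 11 atorvastatin promoter lists, 5 promoter lists and 4 enhancer lists for PCN with atorvastatin. Voom sample weights gave 268 and 171 promoters and 8 atorvastatin enhancers. Also without the 2 libraries, a replicate block gave 124 promoters for PCN (110 higher, 14 lower) and 57 for atorvastatin (42 higher, 15 lower), and 20 (16 lower) and 4 (all lower) enhancers, DESeq2 2 and 2 promoters, limma-voom 1 and 16 promoters and 141 atorvastatin enhancers, a single region per locus 1 PCN enhancer, and loess offsets 2 and 6 promoters. Leaving out a further library gave 3 to 20 and 2 to 20 promoters. With the share of counts in open promoters as a covariate, 1 atorvastatin promoter passed with all 12 libraries, and 2 for PCN and 2 for atorvastatin without the 2 libraries. With split controls, an alternative chosen beforehand, the correlation of the treatments' effects was 0.002 for enhancers and -0.1 for promoters. Without the 2 libraries, chosen afterwards, it was 0.778 and 0.821 (0.65 and 0.603 in simulated unchanged groups), and 0.029 and -0.051 with both changes. The cause was not tested.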

Other observations

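The lists singled out in this part were chosen only after their values were seen, and all values of lists leave out the 2 low-correlation libraries.

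Promoters of sex-biased liver genes, which growth hormone controls in a sex-dependent way, and of PXR/CAR drug metabolism genes stood above random lists of the same CPM with PCN. The sex-biased list had a median log2 fold change of 0.06, where the central 95% of random lists lay at -0.29 to -0.02. The drug metabolism list had 0.11 against -0.12 to 0.05. They were not alone: pericentral (percentile 99.1), periportal (98.8), hepatocyte core (98.3) and fatty acid synthesis (98.2) lists also lay at or above the upper end. With atorvastatin the drug metabolism list, at 0.01, lay at percentile 87.4, and fatty acid oxidation genes, at 0.25 against 0.07 to 0.21, at percentile 99.9. Nuclear receptor (100), pericentral (99.9) and hepatocyte core (97.9) lists lay as high there. Cholesterol synthesis genes lay within the random range for PCN (0.18 against 0.09 to 0.23) and atorvastatin (0.14 against 0.09 to 0.23). By camera without the 2 libraries the sex-biased and drug metabolism lists did not pass for PCN (adjusted p = 0.21 and 0.1, with 17 of 31 and 34 of 55 promoters above 0). Fatty acid oxidation passed for atorvastatin (adjusted p = 2.5e-05, 27 of 35), which was lost with an estimated correlation (0.76). Genes are not independent replicates, so the percentiles carry no p.

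The enhancer regions split into loci of which 146453 held regions of a single width class, and 90385 of these belonged to the class of atorvastatin 3.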
